A study of Mus musculus with 52 samples.

How the data were processed

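Bulk RNA was measured in flash-frozen primary mouse osteosarcomas, with stranded mRNA libraries sequenced as paired reads. RNA was isolated with the Zymo Direct-zol kit per the labels. The deposited table holds raw read counts for 20730 Ensembl genes in 52 libraries, and the authors applied no normalization to these counts. Per the labels, reads were aligned with STAR to the build GRCm38. The versions, the program that counted reads and the gene annotation release are not given in the sources used here. The lowest total of any gene in the table was 260, a mean of 5 per library, so genes of lower counts had been removed upstream. Identifiers were joined to symbols and coordinates of GENCODE M21 on GRCm38, which matched 20668 identifiers and left 62 without a symbol. Symbols shared by several genes affected 14 genes.

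Total counts per library ranged from 21596798 (p53R172H/fl tumour 476) to 67223388 (p53R245W/fl tumour 1813), with a median of 51026968.5. At these depths Trp53 had between 318 and 3504 counts per library.

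Groups were the genotypes in the sample labels. edgeR 4.0.16 in R 4.3.3 fitted all 52 libraries at once with 1 coefficient per genotype, TMM library sizes and robust quasi-likelihood F tests. Genes were kept by filterByExpr with a minimum count of 10, which left 18882 genes. A gene was called changed at an adjusted p (Benjamini-Hochberg) under 0.05. Standard errors are the absolute log2 fold change over the square root of F. CPM and log2 CPM used TMM library sizes, with a prior count of 2 on the log scale. Values within a set come from the same edgeR test on the libraries of that set.

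Lists of genes for p53 targets, for cell types in and around bone and for cell functions were fixed in advance. The 31 lists held 713 entries, of which 696 were in the table, and all 31 had at least 5 tested members. Each was tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, with adjustment over the lists of a comparison. camera with an estimated correlation and fry were run beside it. Trp53 was also compared by two-sided permutation tests with 100000 resamples. The variance explained by genotype was tested by permutation of the genotype labels.

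Named genes followed a fixed rule. Trp53 is named throughout. In each comparison, genes past the threshold with a mean of at least 1 CPM, a regular symbol and a difference of medians of at least 0.5 log2 units in the same direction were ranked. The 8 largest rises, the 8 largest falls and the 5 smallest p-values were taken, with up to 4 called members of each list, or 2 as values where no member was called. From lists that were not called, most of these members are left out for length. Some genes that the rule names are not reported here. Genes outside the rule are Gm23935, Ifi202b, Col1a1, Myc, Xist, Ddx3y, P2rx1, Pimreg and Zfp3, and were chosen after their values were seen.

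The groups, tests, lists, naming rule and first alternatives were chosen before the data were examined. Those alternatives were DESeq2 1.42.0, median-of-ratios (RLE) library factors, no filter, a minimum count of 50, fits of 2 groups alone, limma voom with quality weights, Wilcoxon tests, marker-list covariates, a sex index and surrogate variables of sva 3.50.0. For lists they also included a prior count of 0.5.

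Library sets and matched pairs were found in the data. Sets follow the prefixes of the column names, and set A pools the prefixes FM, FNM, WFM and WFNM. Pairs were matched by Spearman correlation across 12661 genes after removal of set and genotype means, with sex-linked genes left out. The paired fit was added after seeing the data. It used limma voom with library set as a covariate and duplicateCorrelation over matched pairs, which estimated a pair correlation of 0.857. Also added after seeing the data were library set as a covariate, the log2 share of counts at TEC and sense intronic loci as a covariate, fits without set B, sums of matched libraries, fits within each set and fits without the 5 libraries of low Col1a1 (under 13 log2 CPM).

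The tests were tested on simulated data with 200 changed genes. With independent libraries edgeR recovered 77% of the genes changed by a fold of 2 and 98% at a fold of 4, with 18 false calls. With simulated pairs and sets it recovered 40% and 93%, made 69 false calls and called 3682 genes in a comparison of p53R245W/fl with p53fl/fl in which no gene differed. The size of the set effect in that simulation was assumed, not fitted to the real libraries. On the same simulated data the paired fit recovered 50% and 95%, with 14 false calls and 0 in the unchanged comparison. Mean list scores were also compared with matched pair as a random effect (nlme 3.1.168). Overlaps between comparisons were set beside 100 simulations of unchanged groups. No library was left out of the pooled test. That includes p53R172H/fl library 627, with Xist at 727 and the Y-linked Ddx3y at 77.9 CPM, and other libraries that also held both RNAs at lower levels, among them 424, 476, 1241, 1439 and p53fl/fl 1512 and 1522. Whether any of these are mixed samples was not tested.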

Results

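The 52 libraries held RNA from primary mouse osteosarcomas of 3 genotypes. Tumours of the p53fl/fl group carried 2 conditional alleles of Trp53, the gene for the tumour suppressor p53. Tumours of the p53R172H/fl and p53R245W/fl groups carried 1 conditional allele and 1 allele with the named missense change. The groups held 16, 19 and 17 libraries in that order. Column names placed the libraries in 3 sets, called A, B and C here. Set A held 8 p53fl/fl and 8 p53R172H/fl libraries and 0 p53R245W/fl libraries. It pools several prefixes, FM and FNM on its p53fl/fl libraries and WFM and WFNM on its p53R172H/fl libraries. Prefix thus goes with genotype within set A. Set B held 6 libraries of each genotype, and set C held 2, 5 and 11. Within set C, all p53fl/fl and p53R172H/fl libraries carry lane L003 in their names and 10 of 11 p53R245W/fl libraries carry L004 or L005, so lane goes with genotype there. Each of the 18 libraries of set B matched 1 library of set A or C of its own genotype, with Spearman correlations across 12661 genes of 0.703 to 0.926 after removal of set and genotype means. Genes are not independent replicates in such a correlation. Counting each matched pair as 1 unit left 34 units, 10 for p53fl/fl, 13 for p53R172H/fl and 11 for p53R245W/fl. The p-values of the pooled test measure the spread between libraries, some of which match each other. Counts of libraries above or below a median also count both libraries of a pair. The main results are therefore given beside a paired fit, with library set as a covariate and a correlation between matched libraries. Both libraries of a pair have the same genotype, so that fit makes no comparison within pairs.

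Trp53 was higher in both mutant groups than in the p53fl/fl group. The gene (ENSMUSG00000059552.13, GRCm38 chromosome 11, 69580359 to 69591873) gave 14.4 ± 3.9 CPM (read counts scaled to library size, mean ± SD, n = 16) in p53fl/fl libraries. It gave 35.6 ± 6.3 CPM (n = 19) in p53R172H/fl and 37.1 ± 11.2 CPM (n = 17) in p53R245W/fl libraries. The highest p53fl/fl library, at 20.1 CPM, lay below the lowest library of p53R172H/fl, at 26 CPM, and of p53R245W/fl, at 22 CPM. The log2 fold change was 1.30 (SE 0.13, adjusted p 2.11e-09 by edgeR) for p53R172H/fl and 1.36 (SE 0.13, adjusted p 8.51e-10) for p53R245W/fl. A two-sided permutation test of log2 CPM gave p 1e-05 for both, the smallest that 100000 resamples can give, over libraries and also over the 34 units. The paired fit gave 1.28 (SE 0.16, adjusted p 1.05e-06) and 1.27 (SE 0.17, adjusted p 1.47e-05). Within set A the p53R172H/fl value was 1.16 (edgeR adjusted p 0.000989). Within set B the values were 1.32 (adjusted p 0.135) and 1.69 (0.00604), and within set C 1.89 (0.526) and 1.69 (0.936), in smaller groups of libraries. No difference in Trp53 between the mutant groups was called (log2 fold change 0.06, adjusted p 0.742, permutation p 0.87 over libraries and 0.588 over units).

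**Figure D1:**
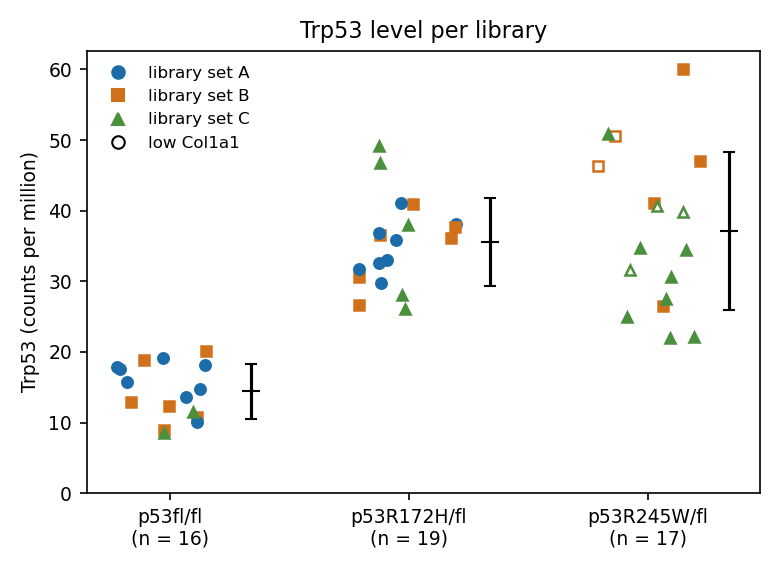
Trp53 in CPM (vertical axis) for each library of the 3 genotypes, with symbols for library sets and open symbols for the 5 libraries of low Col1a1; bars give the mean ± SD. The p53fl/fl libraries lie between 8.5 and 20.1 CPM, below all libraries of the other groups.

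Genotype accounted for a small share of the differences between the tumours. It explained 11.14% of the variance of log2 CPM over the tested genes (permutation p 1e-05, one-sided, the smallest that the permutations can give), against a mean of 3.92% for permuted labels. Labels were permuted over single libraries, which breaks up matched pairs, so this p can be too small. The 34 units explained 90.07% of the variance. Library set explained 8.95% (p 1e-04). After adjustment for set and averaging of matched libraries, genotype explained 11.29%, against 6.06% for permuted labels (p 1e-05). That adjustment was made with the real genotypes and was not redone for permuted labels. Set goes with genotype, so this p can be too small. On the first principal component, 5 p53R245W/fl libraries (numbers 408, 494, 1580, 1831 and 1835) lay apart from the rest. Their Col1a1, the main collagen gene of bone, lay below 13 log2 CPM, while the lowest p53fl/fl library had 13.84. They form 3 of the 34 units, and were singled out after the values were seen. These units were not alike in their list scores, the mean deviation of members from their medians over all libraries. The keratinocyte and epithelial score was 4.25 and 4.08 in 408 and 1835, -0.08 and -0.32 in 494 and 1831, and 1.04 in 1580. The T and NK cell score was -2.32 and -1.89, 3.05 and 2.94, and -1.21 in the same order.

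**Figure D2:**
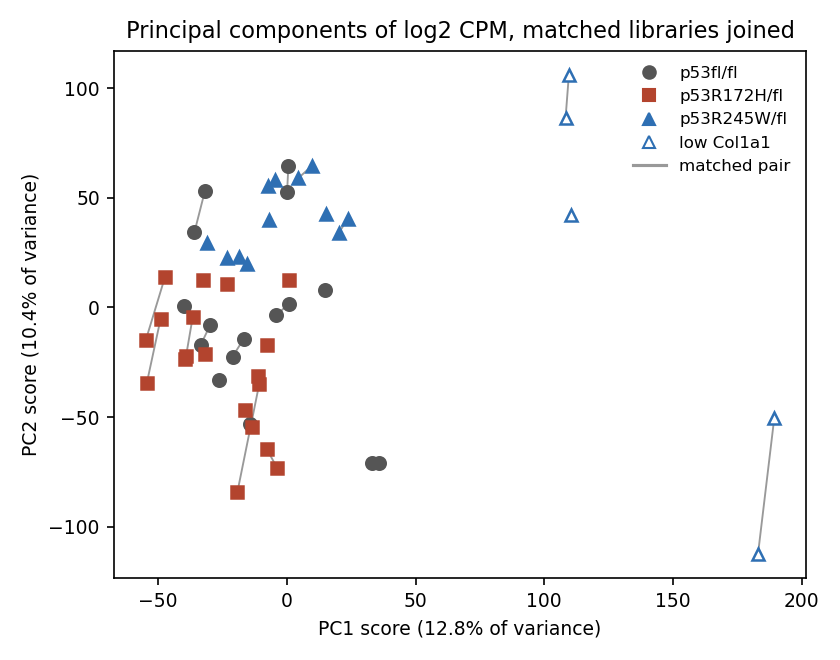
Scores of the 52 libraries on principal components 1 and 2 of log2 CPM (12.8% and 10.4% of variance), coloured by genotype, with matched libraries joined by lines. The 5 open symbols are the p53R245W/fl libraries of low Col1a1, which have the highest scores on component 1.

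The comparison of p53R172H/fl with p53fl/fl sets tumours with this missense allele against tumours with 2 conditional alleles. Apart from Trp53, the list of skeletal muscle genes shifted upward in p53R172H/fl tumours, a call that was lost with an estimated correlation between members (adjusted p 0.526). The fixed list of p53 target genes was not called. No group of the series carried 2 unaltered Trp53 alleles, so this does not show how active p53 targets were in these tumours. Of 18882 genes tested by edgeR, 708 changed, 276 higher and 432 lower, and 254 of them by at least 1 log2 unit. With library set as a covariate the count was 910 (358 higher and 552 lower), with RLE factors 663 (300 and 363) and with DESeq2 1174 (595 and 579). The paired fit called 2 genes, Trp53 and the small RNA gene Gm23935, and 1699 genes had an unadjusted p under 0.05 there. Within the sets edgeR called 96 genes in A, 1 in B and 0 in C, with 2350, 1666 and 1361 at an unadjusted p under 0.05.

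Skeletal muscle genes, which encode the contractile apparatus of muscle fibres, had the smallest adjusted p of the lists by camera. Of 25 members tested, 13 rose over all genes and 22 rose when adjusted over the list alone, with a median log2 fold change of 1.88 (camera adjusted p 1.01e-21, and 0.526 with the estimated correlation). The calcium pump Atp2a1 rose by 2.54 (SE 0.65, adjusted p 0.0197), the thin filament gene Neb by 2.20, Actn3 by 2.19 and the myosin light chain Mylpf by 1.94. Atp2a1 lay above the p53fl/fl median in 18 of 19 libraries. The muscle regulator Myf6 rose by 2.72. The median of the list was 1.64 within set B and 2.16 in the paired fit. The list score ran from -4.745 to 1.919 in p53fl/fl libraries and from -2.823 to 4.11 in p53R172H/fl libraries. Whether tumour cells or other cells in the samples carried this RNA was not tested. The same test called 3 more lists as higher. The T and NK cell list (adjusted p 5.13e-03, median 0.81), the B and plasma cell list (0.0497, median 0.45) and the adipocyte list (0.0137, median 0.07) had 0 members called by edgeR, over all genes or adjusted over the list alone. With an estimated correlation each of these 3 had an adjusted p of 0.985, and the B and plasma cell list also lost its call in 8 other settings, among them RLE factors (0.0714), library set as a covariate (0.104) and the fit without the 5 libraries of low Col1a1 (0.0501). The other 27 lists had adjusted p-values of 0.097 to 0.954, and 14 of their 609 members changed. Among them the interferon response list (0.114) was called higher with the share of counts at TEC and sense intronic loci as a covariate (0.00988). TEC and sense intronic are gene types of the annotation. The p53 target list had an adjusted p of 0.711 with 1 of 38 members higher, the long noncoding RNA Pvt1, both over all genes and adjusted over the list alone.

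The largest rises were in the adhesion gene Cdh19 (4.22), Gpat2 (3.39), Raver2 (3.35), the proteasome subunit Psma8 (3.21), Asxl3 (2.99), Pvt1 (2.99), the channel gene Best3 (2.84) and Myf6. Pvt1, which neighbours Myc, reached 1370 CPM in 1 p53R172H/fl unit, against medians of 24.6 CPM in p53R172H/fl and 15.2 CPM in p53fl/fl units. Among the largest falls were Nrk (-5.80), the homeobox gene Lhx9 (-5.29), Nell2 (-4.67), the complement gene Hc (-4.41), Krt17 (-4.02) and the cytokine Il11 (-3.08). Between 3 and 8 of the 19 p53R172H/fl libraries lay above the p53fl/fl median for these genes. Within set C, Nrk, Hc and Krt17 were higher, by 2.05, 0.62 and 0.72, in a set with 2 p53fl/fl libraries.

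Genes with the smallest p differed in most libraries. Fmr1, which encodes an RNA-binding protein of translation control, was lower in all 19 p53R172H/fl libraries than the p53fl/fl median (log2 fold change -0.62, SE 0.09, adjusted p 4.38e-05, and 0.161 in the paired fit). The glycosylation chaperone C1galt1c1 was also lower in all 19 (-0.83). Atp1b2, a sodium pump subunit encoded next to Trp53 (chromosome 11, 69599736 to 69605942), rose by 2.54 (SE 0.38, adjusted p 5.73e-05, and 0.164 in the paired fit). AA465934 rose by 1.77 and lay above every p53fl/fl library in 17 of 19. The list of osteosarcoma-associated genes was not called (median 0.01, adjusted p 0.675). Of its 30 members 3 rose, Trp53, the cell cycle regulator E2f3 (1.08) and the adhesion gene Lsamp (2.52), and 5 rose and 4 fell adjusted over the list alone.

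The comparison of p53R245W/fl with p53fl/fl sets tumours with the other missense allele against the same p53fl/fl tumours. The lists of mitochondrial respiration, of the proteasome and of cholesterol synthesis shifted upward, and those of bone matrix and osteocytes downward. All these list calls were lost with an estimated correlation (adjusted p 0.44 to 0.608). The 8 largest rises were smaller without the tumours of low Col1a1, and 5 of them lost their call there, while Ank2 rose and Hjurp fell in the paired fit too. By edgeR 3365 genes changed, 1889 higher and 1476 lower, and 1547 of them by at least 1 log2 unit. Without the 5 libraries of low Col1a1 the count was 2255 (933 higher and 1322 lower), of which 1715 were among the 3365, and with the share of TEC and sense intronic counts as a covariate it was 1103 (819 and 284). With library set as a covariate it was 1005, near the 910 of the previous comparison, and the paired fit called 3, with 1996 at an unadjusted p under 0.05. Within set B edgeR called 4 genes and within set C 0 (2070 and 551 at an unadjusted p under 0.05), and set A holds none of these tumours.

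Trp53, Ank2 and Hjurp were the 3 genes called by the paired fit. Ank2 (chromosome 3, 126921612 to 127499350), which encodes an adaptor that anchors membrane proteins to the cytoskeleton, rose by 2.23 (SE 0.32, adjusted p 1.8e-05). The paired fit gave 2.37 (SE 0.35, adjusted p 0.000135), and sets B and C gave 2.68 and 2.09. Its median over units was 62.5 CPM in p53R245W/fl, 12 in p53fl/fl and 14.3 in p53R172H/fl. Hjurp (chromosome 1, 88262471 to 88277633), the chaperone that loads the centromeric histone, fell in all 17 libraries below the p53fl/fl median (-1.25, SE 0.17, adjusted p 5.77e-06). The paired fit gave -1.16 (SE 0.19, adjusted p 0.00072). AA465934 rose by 2.35 and the respiratory subunit Ndufb6 by 1.09, with paired adjusted p-values of 0.091 and 0.0662.

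Of 30 oxidative phosphorylation genes, which encode the respiratory chain, 22 rose over all genes and 26 rose adjusted over the list alone (median 0.51, camera adjusted p 1.63e-15, and 0.44 with an estimated correlation). Cox4i1 rose by 0.94, Ndufs4 by 0.91, Cox5b by 0.86 and Cox7b by 0.85, and the first 3 lay above the p53fl/fl median in 17 of 17 libraries. Of 26 proteasome genes, which encode the main protease of the cytosol, 11 rose, and 18 adjusted over the list alone (median 0.35, adjusted p 5.96e-09, and 0.593 with an estimated correlation). Psma2 rose by 1.21, Psmb4 by 0.91, Psma6 by 0.64 and Psma5 by 0.62. Of 24 cholesterol synthesis genes 8 rose, and 15 adjusted over the list alone (median 0.52, adjusted p 3.07e-06, and 0.44 with an estimated correlation). Idi1 rose by 0.95, Hmgcs1 by 0.89, Fdft1 by 0.74 and Mvk by 0.59. With the share of TEC and sense intronic counts as a covariate, the called members of the respiratory and proteasome lists fell from 33 to 3, and the proteasome list lost its call (adjusted p 0.0544) while the respiratory list kept it (4.02e-06). The mean of both lists was higher by 0.48 (SE 0.12), by 0.25 (SE 0.12) with that covariate and by 0.04 (SE 0.13) with library set added. The medians of the 3 lists within set B were 0.48, 0.33 and 0.41, and in the paired fit 0.34, 0.23 and 0.41.

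The osteoblast and mineralising matrix list was lower (median -0.44, adjusted p 3.07e-06), with 2 of 28 members lower, and 1 adjusted over the list alone. Col24a1, a collagen of bone, fell by 1.64 and the Wnt receptor Lrp5 fell by 0.60. The osteocyte list was lower (median -0.80, adjusted p 0.0133), with 2 of 13 members lower on both counts, the matrix protein Dmp1 (-2.05) and Slc8a3 (-1.10). The TGF-beta and BMP signalling list was lower (median -0.41, adjusted p 0.0143), with 1 of 26 members higher and 3 lower on both counts, among them Bmp4 (-1.29), Ccn2 (-1.24) and Smad7 (-0.54). With an estimated correlation these 3 lists each had an adjusted p of 0.608. Without the 5 libraries of low Col1a1 their adjusted p-values were 0.784, 0.687 and 0.508. The mitosis list was higher (median 0.22, adjusted p 9.14e-03), with 4 of 26 members higher on both counts, Ccnb1, Ccnb2 (0.68), Cdc20 (0.66) and Ube2c (0.65). Without those 5 libraries its adjusted p was 0.0644. The skeletal muscle list was higher (median 0.57, adjusted p 0.0384) with 0 of 25 members called by edgeR, over all genes or adjusted over the list alone. Its median within set B was 0.03, and its adjusted p was 0.418 with library set as a covariate, 0.137 over means of matched libraries and 8.3e-09 without the 5 libraries of low Col1a1. With an estimated correlation the mitosis and muscle lists each had an adjusted p of 0.951. The p53 target list had an adjusted p of 0.361, with 6 of 38 members higher and 5 adjusted over the list alone, among them Perp (4.93), Plk2 (1.13) and Ei24 (0.55). Perp had an adjusted p of 0.117 without the 5 libraries. The keratinocyte and epithelial list was not called (adjusted p 0.437, and 0.989 without those libraries). Of its 11 members 3 were higher, and 5 adjusted over the list alone (median 1.35). All 23 lists that were not called had adjusted p-values of 0.162 to 0.904, with 52 of 486 members changed. Among them the osteoclast list (0.748) and the hypoxia and glycolysis list (0.167) were called higher without the 5 libraries of low Col1a1 (4.49e-05 and 0.0448). The interferon response, macrophage and matrix remodelling lists were called lower with the TEC and sense intronic share as a covariate (3.75e-08, 3.55e-05 and 0.000268). With library set as a covariate the neutrophil (0.00129) and erythroid (0.0402) lists were called lower and the DNA replication list (0.0402) higher.

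The largest rises were in Sfrp5 (8.85), Frmpd1 (8.67), Fat2 (8.61), Cldn1 (7.78), Dpysl5 (7.55), Ngfr (7.45), Coch (6.86) and Frem2 (6.65). Without the 5 libraries of low Col1a1 the values fell to 1.08, 1.78, 1.19, 0.96, 2.84, 1.80, 0.61 and 2.29, and Dpysl5, Ngfr and Frem2 were still called (adjusted p 0.0125, 0.0158 and 0.0346). Among the largest falls were Lhx9 (-4.85), Nell2 (-4.31), the cadherin Cdh22 (-4.11), Cadps2 (-3.39), Ppef1 (-3.38), Il11 (-2.79) and the sterol transporter Abcg8 (-2.78). These genes had paired adjusted p-values of 0.41 or more, and Nell2 had a paired value of 0.07. Within set C, Il11 (1.13) was higher.

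**Figure D3:**
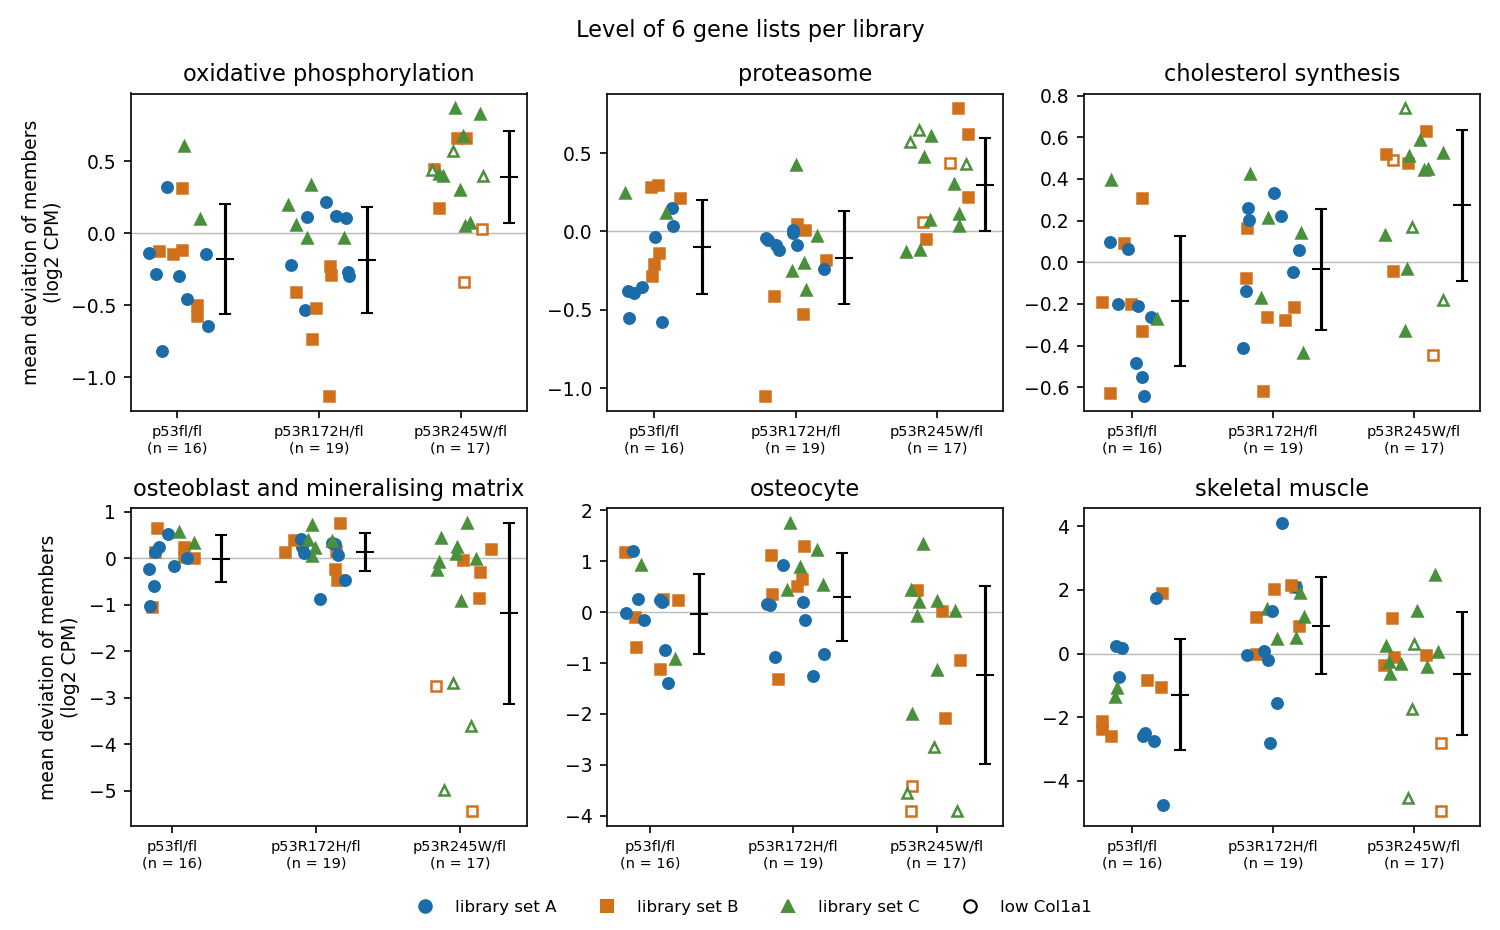
Mean deviation of the members of 6 gene lists from their medians over all libraries (vertical axes, log2 CPM) for each library, with symbols for library sets and open symbols for the 5 libraries of low Col1a1; bars give the mean ± SD. The osteoblast score reaches -5.44 in a library of low Col1a1, while the lowest p53fl/fl library has -1.04.

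The comparison of p53R245W/fl with p53R172H/fl sets the missense alleles against each other, and it held the largest number of changed genes. The respiratory, proteasome and cholesterol lists shifted upward in p53R245W/fl tumours, and the osteoblast, osteocyte and skeletal muscle lists downward. All 6 list calls were lost with an estimated correlation (adjusted p 0.874 to 0.983), and the 3 downward calls also without the 5 libraries of low Col1a1 (0.15, 0.343 and 0.0822). By edgeR 5829 genes changed, 3435 higher and 2394 lower, and 2193 of them by at least 1 log2 unit. The paired fit called 293 genes, 117 higher and 176 lower, and 288 of them were among the 5829. Within set B edgeR called 609 genes, of which 596 were among the 5829, and within set C it called 0 (3136 at an unadjusted p under 0.05). Without the 5 libraries of low Col1a1 edgeR called 4276 genes (2038 higher and 2238 lower) and the paired fit 16 (13 and 3).

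Of 30 oxidative phosphorylation genes 20 rose, and 29 adjusted over the list alone (median 0.56, adjusted p 5.7e-12). Cox4i1 (1.06), Cox5b (0.89), Ndufv2 (0.86) and Atp5c1 (0.65) had the smallest p. Of 26 proteasome genes 19 rose, and 21 adjusted over the list alone (median 0.47, adjusted p 5.09e-09), with Psma6 (0.78), Psmb1 (0.77), Psma5 (0.74) and Psmd14 (0.67). Both lists had an adjusted p of 0.874 with an estimated correlation. The share of TEC and sense intronic counts was also lower here (medians 0.304% in p53R172H/fl and 0.152% in p53R245W/fl), and with it as a covariate the called members of both lists fell from 39 to 7. The mean of both lists was higher by 0.48 (SE 0.11), by 0.24 (SE 0.12) with that covariate and by 0.05 (SE 0.13) with library set added. The medians within set B were 0.81 and 0.67, and in the paired fit 0.28 and 0.23. The paired fit called 0 members of either list. Of 24 cholesterol synthesis genes 5 rose, and 3 adjusted over the list alone (median 0.31, adjusted p 0.0177, 0.983 with an estimated correlation, 0.103 over means of matched libraries and 0.104 with the TEC and sense intronic share as a covariate). Hmgcs1, which makes an early intermediate of the pathway, rose by 1.06 (SE 0.16, adjusted p 6.28e-06) and by 0.88 in the paired fit (SE 0.20, adjusted p 0.0259). That fit gave 0.90 without the 5 libraries of low Col1a1, with the call lost in fewer libraries (adjusted p 0.08). Fdft1 rose by 0.67 and Acat2 by 0.66.

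Of 28 osteoblast and mineralising matrix genes, 1 rose and 7 fell, with the same counts adjusted over the list alone (median -0.64, adjusted p 1.48e-05). Lrp5 fell by 1.21 (SE 0.21, adjusted p 4.2e-05). Lrp5 and Col24a1 (-1.84) had paired adjusted p-values of 0.0454 and 0.0377, and the transcription factor gene Dlx3 (-1.25) had 0.0644. The paired calls of Lrp5 (-0.64, adjusted p 0.176) and Col24a1 (-0.97, adjusted p 0.279) were lost without the 5 libraries of low Col1a1. Of 13 osteocyte genes, 1 rose and 5 fell, and 6 fell adjusted over the list alone (median -0.96, adjusted p 0.0177). Dkk1, which encodes a secreted Wnt inhibitor, fell by 3.36 (SE 0.85, adjusted p 0.00241, and -4.51 with adjusted p 0.0353 in the paired fit). Without those libraries the paired value was -3.15, and the call was lost (adjusted p 0.175). Both lists had an adjusted p of 0.968 with an estimated correlation. Without the 5 libraries of low Col1a1 the adjusted p-values were 0.15 and 0.343. Of 25 skeletal muscle genes 8 fell, and 16 adjusted over the list alone (median -1.35, adjusted p 1.9e-05, and 0.983 with an estimated correlation). Ttn (-2.11), Casq1 (-2.10), Atp2a1 (-1.82) and Neb (-1.72) fell. The muscle list had an adjusted p of 0.0822 without those 5 libraries. In the paired fit its median was -1.015, and 0 of its members were called. The p53 target list had an adjusted p of 0.672, with 7 of 38 members higher and 1 lower, and 4 and 1 adjusted over the list alone. The keratinocyte and epithelial list was not called (adjusted p 0.352, and 0.906 without those libraries), with 6 of 11 members higher on both counts (median 1.895). The 25 lists that were not called had adjusted p-values of 0.166 to 0.975, and 102 of their 538 members changed, and among them the osteoclast list (0.65) was called higher and the T and NK cell list (0.216) lower without the 5 libraries (0.000151 and 0.0388). With the TEC and sense intronic share as a covariate the interferon response, macrophage, and T and NK cell lists were called lower (1.77e-13, 0.000117 and 0.00122). With library set as a covariate the B and plasma cell (0.0242), neutrophil (0.0134) and interferon response (0.024) lists were called lower and the mitosis list (0.0292) higher.

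The smallest p-values belonged to genes that differed across the group. Pdcd10 (chromosome 3, 75516490 to 75556856), a gene of vascular integrity, rose by 1.08 (SE 0.14, adjusted p 1.98e-06) and lay above the p53R172H/fl median in 17 of 17 libraries. Srgap2 (-0.78) and the protease gene Adamts10 (-1.23) lay below that median in 17 of 17. The paired fit called these 3 genes, with adjusted p-values of 0.0183, 0.0209 and 0.0299. That fit gave 0.86, -0.67 and -0.89, and 0.79, -0.54 and -0.84 without the 5 libraries of low Col1a1, where Srgap2 and Adamts10 lost the call (adjusted p 0.0402, 0.0576 and 0.12). The largest rises were in Fat2 (10.99), Lhx8 (9.34), Cldn1 (7.45), Coch (7.20), Ngfr (6.71), Dpysl5 (6.32), the neuropeptide gene Cartpt (5.94) and Clic6 (5.85). Without the 5 libraries of low Col1a1, Fat2 (3.62), Lhx8 (5.65) and Cartpt (6.45) were still called, and the other 5 were not. The largest falls were in Rnf17 (-4.88), Cdh12 (-4.18), Cdh19 (-3.63), Ccnb3 (-3.36), Dkk1, Grik2 (-3.23), the interferon-inducible gene Ifi213 (-2.84) and Ighg1 (-2.70). Without those libraries all 8 but Ighg1 (adjusted p 0.081) were still called.

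Ifi202b (chromosome 1, 173962568 to 173982744), an interferon-inducible gene, was named after its values were seen. It reached at least 1 CPM in 11 of 11 p53R245W/fl units, 4 of 13 p53R172H/fl units and 4 of 10 p53fl/fl units. Its median was 30.1 CPM in p53R245W/fl units, 0.377 in p53R172H/fl and 0.621 in p53fl/fl. Against p53R172H/fl the paired fit gave 6.36 (SE 1.24, adjusted p 0.0147) and edgeR 3.81 (adjusted p 0.00122). Against p53fl/fl edgeR gave 2.47 (adjusted p 0.0494), and the paired fit, which did not call Ifi202b there, 4.97 (adjusted p 0.0685), or 5.40 (adjusted p 4e-04) without the 5 libraries of low Col1a1.

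Both missense alleles were compared with the same p53fl/fl tumours, so their changes can be set side by side. Of the genes called against p53fl/fl, 131 changed in the same direction in both comparisons, 42 higher and 89 lower, and 14 in opposite directions. Independent lists of these sizes would share 27.6 higher and 33.8 lower genes. Both comparisons use the same p53fl/fl libraries, which raises the overlap. With the p53fl/fl libraries split into 2 sets of 8, 504 and 58 genes were called and 2 were shared in direction, against 0.8 for independent lists. Simulated groups with no change, tested by limma against a shared group, had a mean of 3.7 and at most 180 genes in common. Of 100 simulations, 2 reached the 73 that limma found. The log2 fold changes of both comparisons had a correlation across genes of 0.229 and a covariance of 0.068. The simulated means were 0.524 and 0.093, with a covariance range of 0.028 to 0.202. Trp53, AA465934, Lhx9, Nell2, Il11 and Ccn2 were among the genes called in the same direction.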

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

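The settings that use library set, matched pairs, parts of the libraries, the share of TEC and sense intronic counts or the 5 libraries of low Col1a1 were chosen after seeing the data, and the others before. For all changes below the cause was not tested, except that settings within a set or without set B use fewer libraries. Trp53 kept its direction and its side of the threshold with RLE factors, DESeq2 and the paired fit. The variance explained by genotype kept a p of 1e-05 over its 4 alternatives, at 10.66% to 16.5%. The alternative with set adjustment permuted labels only after that adjustment, so its p can be too small. The other alternatives and the main test permuted labels over single libraries, which breaks up matched pairs, so their p can be too small too. For p53R172H/fl against p53fl/fl (708 genes), DESeq2 called 1174, marker-list covariates 349, surrogate variables 2696, the paired fit 2, the fit without set B 36, that fit with library set as a covariate 53, and summed matched libraries 43. Sets A, B and C alone gave 96, 1 and 0. Leaving out the libraries of low Col1a1 gave 1171, and 16 with the paired fit. For p53R245W/fl against p53fl/fl (3365 genes), Wilcoxon tests called 1620, surrogate variables 5737, library set as a covariate 1005, the share of TEC and sense intronic counts as a covariate 1103, the paired fit 3, the fit without set B 2125, that fit with library set 1, and summed libraries 1803. Sets B and C gave 4 and 0, and the paired fit without the libraries of low Col1a1 gave 10. For p53R245W/fl against p53R172H/fl (5829 genes), the share of TEC and sense intronic counts as a covariate called 1652, the paired fit 293, the fit without set B 2715, that fit with library set 0 (3284 at an unadjusted p under 0.05 by edgeR), summed libraries 2970, sets B and C 609 and 0, and the paired fit without the libraries of low Col1a1 16. Gene lists called with an estimated correlation numbered 0, 0 and 0 in the 3 comparisons, against 4, 8 and 6 with the preset correlation, and fry called 1, 6 and 5. Marker-list covariates gave 8 lists in the first comparison, and library set as a covariate 10 in the third. The overlap of 131 genes became 211 with DESeq2, 756 with surrogate variables, 62 with an absolute log2 fold change of at least 1, and 71 with library set as a covariate. Of 122 called results of genes named in the text, the paired fit kept the call in 9, and 112 kept direction alone. RLE factors kept the call in all 122. Reversed log2 fold changes were as follows. Against p53fl/fl, Gli1 in p53R245W/fl had -0.14 with DESeq2 and -0.77 without the libraries of low Col1a1. Prim1 had -0.34 in both of these and -0.33 in the paired fit without those libraries. Il11 had 0.29 without set B and with library set, and Nell2 had 0.068 in the paired fit and 0.45 in that fit without those libraries. Against p53R172H/fl, Gli1 had -0.24 with quality weights, -0.053 with surrogate variables, -0.47 without those libraries and -0.23 in the paired fit without them. Krt17 had -0.29 with quality weights, -0.77 with the sex index, -0.10 without those libraries and -0.31 in the paired fit without them. Prim1 had -0.003 with DESeq2 and -0.18 in the paired fit without those libraries. Library totals ran from 21596798 to 67223388 counts, and depth was not varied, so what depth limits, such as calls of genes with few counts, was not measured.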

Other observations

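The tests of the presence of Ddx3y and of the correlation between unpaired libraries were chosen only after the result was seen. So were the tests of the TEC and sense intronic share, alone and with library set, and the test of Gli1 and Prim1. For the gene lists and for Cdk4, the requirement that a value clear its bound by 1 standard error, with pair as a random effect where pairs are present, was also added after the values were seen, and it left Cdk4 open; with 2 standard errors library set would be open too.

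Each library of set B matched 1 library of another set. The highest correlation of an unpaired couple was 0.489, below the lowest of a pair, 0.703. This gap does not test whether libraries of 1 genotype merely resemble each other. Genotype means had been removed, so a resemblance shared by a whole genotype could not appear, and each pair was the best match in the same correlations. A library entered more than once is argued against by the counts, whose lowest chi-square per degree of freedom in a pair was 137. The presence of Ddx3y, a Y-linked gene not used for matching, was the same in 18 of 18 pairs, against 9.5 for random pairs within a genotype. A candidate explanation is that both libraries of a pair come from 1 tumour or 1 animal, and the labels give each library its own number.

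Oxidative phosphorylation and proteasome genes were higher in p53R245W/fl than in p53fl/fl tumours (median of the 56 members 0.46; mean per library higher by 0.48, SE 0.12). Short transcripts are argued against by random lists matched on transcript length and mean expression, of which 100% of 10000 had a lower median, and the 5 libraries of low Col1a1 by a median of 0.49 without them. Library set as the whole cause is argued against by a median of 0.38 within set B, with 56 of 56 members higher (mean 0.40, SE 0.18), though 0 single members were called there by edgeR, in fewer libraries; with set as a covariate the mean was 0.33 (SE 0.13) and 12 members were called. A share of unspliced RNA stays open, because unspliced reads were not counted. The share of counts at TEC and sense intronic loci (gene types of the annotation) was used in their place. Whether it follows unspliced RNA was not tested. With that share as a covariate the median was 0.25 and the mean 0.25 (SE 0.12). With library set added the mean was 0.04 (SE 0.13), so the higher level was not kept. That share itself goes with genotype (medians 0.326% in p53fl/fl and 0.152% in p53R245W/fl), so it could be a cause or a companion of the change.

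Cdk4 (chromosome 10), Gli1 and Prim1 were called higher in p53R245W/fl than in p53fl/fl tumours. Cdk4 reached 4761 and 8698 CPM in p53R245W/fl libraries 408 and 1835, a matched pair. In these libraries the other 40 genes within 1 Mb of Cdk4 were higher by a median of 4.43 log2 units, and 37 of them by more than 1, while 6 of 69 genes at 5 to 20 Mb were. A gain of a chromosome 10 segment in 1 tumour may explain the rise. Without these libraries the median difference was 0.37 for Cdk4 (SE 0.23, against a p53fl/fl SD of 0.51), and the higher of the differences of Gli1 and Prim1 was -0.01 (SE 0.35), so a smaller rise in the other tumours is neither shown nor excluded.

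Genes near Trp53 were called in the same direction in both comparisons with p53fl/fl in 4 of 359 cases within 10 Mb. Elsewhere 125 of 18470 were (one-sided Fisher test p 0.23). The 4 were P2rx1, Pimreg, Atp1b2 and Zfp3, named after their values were seen. Linkage to the engineered locus cannot be told apart from chance with so few genes.

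Random splits of the samples tested whether chance could give as many calls. For p53R172H/fl against p53fl/fl, 1 of 100 splits of the libraries gave as many genes as the real 708 (the real split itself), and the highest other gave 104. With pairs kept together, 2 of 100 did, and the highest other gave 1490, more than the real count, which points to a structure of the samples beside genotype. For p53R245W/fl against p53fl/fl, 1 of 100 splits reached 3365 in both designs, and the highest others gave 1564 and 2473. For p53R245W/fl against p53R172H/fl, 1 of 100 reached 5829 in both, and the highest others gave 1091 and 4009. No more than 2 of 100 splits thus reached a real count, the real split included. Splits of single libraries broke up the matched pairs, and their highest counts lay below those of splits that kept pairs together. The splits do not hold library set, which goes with genotype, so they cannot exclude chance. Simulated pairs and sets gave 3682 calls in a comparison of p53R245W/fl with p53fl/fl without a change. The simulated set effect had an assumed size, so that count cannot be ranked against the real 3365. For p53R172H/fl against p53fl/fl the same simulation gave 69 false calls, and for p53R245W/fl against p53R172H/fl its calls were not counted. Library set stays open as a source of calls. The median other split called 0, 47 and 61 genes with pairs broken up, and 60, 598 and 376 with pairs kept together. Matched libraries thus raised the calls of random splits. How many of the real calls they account for was not measured.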
